A study of Mus musculus with 35 samples.

How the data were processed

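Liver RNA of 35 mouse samples was measured on Affymetrix Mouse Gene 1.1 ST arrays, the platform that the identifier in the probe annotation stands for, with 1 array per sample. Per the labels' protocols, livers were dissected into tumor and non-tumorous tissue (NTL), snap frozen, and the tumor tissue was checked by histology. RNA was isolated with the Directzol kit, kept when its RNA integrity number was above 8.0, and 100 ng per sample were labelled with biotin.

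The deposited values are on the log2 scale and were made by the authors with RMA (background correction, quantile normalization and summary per probe set), per the submitters' processing notes. The software version, and whether all arrays were normalized together, are not given in the sources used here. Values ran from 1.81 to 14.3 over the arrays, and the array medians over all probe sets lay between 5.59 and 5.73. An array has no read depth, so the number of arrays limits the precision of each value.

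Of 35556 probe sets, 21218 carried 1 gene symbol, 1881 several and 12457 none in the annotation table. The 18820 genes tested are those with a probe set of their own, and for 1386 genes with more than 1 such probe set the brightest was taken. Nusap1, the gene in the title of the series, had no probe set of its own: both of its probe sets are annotated to Nusap1 and to its neighbour Oip5, so they were analysed as a pair of extra features. Coordinates come from the RefSeq table of assembly GRCm38.p6. No filter on dim genes was applied. A change against a group mean below the first quartile of every array (4.13 to 4.24) is near the lower limit of the arrays and tells its direction rather than its size. Among the genes named this held for Klrb1b, Gldn and Csn3 against DEN controls, Lta in DEN tumors, Aqp7, Igf2bp3 and Ckap2 in LT NTL and Prc1 in MYC NTL. It also held for Hsd3b5, Slco1a1, Eif2s3y and Uty in LT tumors against controls, and for Cidea in DEN controls and in the LT and MYC groups.

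Samples fell into 8 groups by the labels: DEN_control, DEN_NTL and DEN_tumor with 5 arrays each, LTMYC_control with 4, LT_NTL with 5, LT_tumor with 3, MYC_NTL with 3 and MYC_tumor with 5. The MYC_NTL arrays were kept as labelled, although their mouse identifiers begin with WT. The groups were compared with limma 3.58.1 in R 4.3.3: lmFit with a mean per group over all 35 arrays, moderated tests by eBayes, and Benjamini-Hochberg adjustment over the 18820 genes, with a gene called at an adjusted p under 0.05. Errors beside log2 changes are standard errors of this fit, and errors beside group means are standard deviations. Each tumor group was compared with its NTL and its control group, each NTL group with its controls, and the 3 tumor minus NTL changes with each other. The LT and MYC groups share 4 control arrays. For the Nusap1 and Oip5 feature an exact two-sided permutation test of the difference of means was added.

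A total of 37 gene lists, written before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, again with a correlation estimated per list, and with fry. They cover cell division, liver metabolism, zonation, inflammation, cell types, stress responses, the clock and sex. Camera compares a list with all other genes. Fry asks whether the genes of a list move on balance in a direction, without comparing them with other genes, and its results are given among the alternatives. Members were also counted after adjustment over the list alone. The choice of groups, tests, lists and the alternatives tried was made before the data were examined, apart from those named in the closing section. The named genes of a tumor to NTL comparison are the 8 called genes with the largest rise and the 8 with the largest fall. In the other comparisons they are the 5 with the largest rise and the 5 with the largest fall. To these came the 8 genes with the largest mean change in each direction among those called in all 3 models, up to 4 members per list in the direction of most called members and 1 in the other, and a fixed set that included Mki67, Top2a, Afp, Gpc3, Igf2, Glul, Alb, Myc, Lta, Ltb, Cdkn1a, Krt19, Cd79a and Col1a1. Genes of the Cyp, Ugt and Serpina families were kept, although they have near-identical paralogs that probe sets can share. Predicted genes, clone names, and histone, olfactory, antigen receptor and major urinary protein genes were left out of the ranking by size. Further genes are named in the closing section, which says that they were chosen later.

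The fits were tested on simulated data with the real genes' means and spreads and 200 changed genes. Of the genes changed by 1 log2 unit, 94% were recovered in DEN tumor against NTL, 86.6% in LT tumor against NTL and 92.5% in MYC tumor against NTL. Of those changed by 0.5, 59.7%, 55.2% and 62.7% were recovered. Between 3 and 22 of the 18590 to 18605 unchanged genes were called in the 9 comparisons of groups. A list shifted by 0.5 was recovered in each simulated comparison. The simulation gave each gene the same spread in all groups and drew genes and arrays independently. In the data the median spread of a gene was 0.189 in LT tumors and 0.097 in MYC NTL, and some tumor arrays share a mouse identifier stem. The simulation therefore shows how the fit behaves when its assumptions hold, not how many calls in these data are right.

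The alternatives were median centring, quantile normalization within each experiment, the mean of all probe sets of a gene, a filter that left out the dimmest 40% of genes, a fit to the compared groups alone, a trended and robust variance, array quality weights, arrays with a shared mouse identifier stem averaged or taken as a random block, the replicate number as a block, other thresholds, and leaving out each array. Mouse identifiers share a stem in tumor replicates 1 and 4 and in replicates 3 and 5 of the DEN group, and in tumor replicates 1 and 2 of the LT group. Alternatives chosen after the data were examined were the Xist level as a covariate, a fit without the high-Xist controls, a fit with only the high-Xist LT arrays, the difference of the clock arms as a covariate, and the permutation test and the splits with arrays of a shared stem averaged. Probe sets with several symbols or none were not tested by name, and the miRNA part of the study was not analysed here.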

Results

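The series compares liver RNA from 3 mouse models of liver cancer, and its title names the gene Nusap1. In the DEN model, mice received diethylnitrosamine, a carcinogen activated in hepatocytes, at 10 mg per kg on day 15 and were followed to 9 months. In the LT model, mice carry a transgene for lymphotoxin alpha and beta in the liver and were followed for 12 months. In the MYC model, a MYC transgene in hepatocytes is held off by doxycycline chow (200 mg per kg) until 8 weeks and is active afterwards. By the labels, tumor and non-tumorous liver (NTL) were taken from each model, together with liver of untreated controls. No mouse identifier stem is shared between the tumor and NTL arrays of a model. By the identifiers, tumor and NTL therefore come from different animals, and their comparison cannot separate tissue from animal or collection. The mouse identifiers of the MYC NTL arrays begin with WT, so whether these livers come from MYC mice or from wild-type mice is not settled. There were 5 arrays each of DEN control, DEN NTL, DEN tumor, LT NTL and MYC tumor, 4 of the controls shared by the LT and MYC models, and 3 each of LT tumor and MYC NTL. The labels call the controls matched for sex and age. Xist, the RNA of the inactive X chromosome, was between 11.7 and 12.2 on the log2 scale in 9 arrays and at most 6.24 in the other 26. The 9 arrays were all 3 LT tumors, LT NTL replicates 1, 3, 4 and 5, and replicate 3 of each control group. The number of arrays limits the precision of each value.

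The first question was whether Nusap1, which encodes a protein that binds spindle microtubules, differs between tumor and NTL. Nusap1 lies on chromosome 2 at 119618298 to 119650165, next to Oip5 at 119609532 to 119618505 (GRCm38.p6), and both probe sets are annotated to both genes. The brighter probe set rose in the tumors of each model. It was higher than in NTL by 1.69 ± 0.31 log2 units in DEN tumors (5 against 5 arrays), by 1.71 ± 0.36 in LT tumors (3 against 5) and by 3.11 ± 0.36 in MYC tumors (5 against 3). The limma adjusted p was 8.2e-05, 0.000982 and 4.12e-07, and the exact two-sided permutation p was 0.00794, 0.0179 and 0.0179, the smallest that these group sizes allow. These p-values take each array as an animal, but some DEN and LT tumors share a mouse identifier stem. With such arrays averaged, the exact permutation p was 0.0179 in DEN (3 against 5 values) and 0.0476 in LT (2 against 5), again the smallest possible. Group means in tumors were 6.69 ± 0.90, 6.41 ± 0.91 and 7.87 ± 0.53 in the same order, and control means were 4.71 ± 0.19 in DEN controls and 4.94 ± 0.32 in the shared controls. Against controls the rises were 1.98 ± 0.31 in DEN, 1.47 ± 0.37 in LT and 2.94 ± 0.33 in MYC tumors. The LT call against controls had an adjusted p of 0.00761, which became 0.0706 without LT tumor replicate 2 and 0.158 when only these groups entered the fit, and the permutation p with stems averaged was 0.0667 (2 against 4 values, the smallest possible). NTL differed from controls by 0.29, -0.24 and -0.17, and none of these passed the test. The dimmer probe set had means of 3.43, 3.43 and 3.46 in DEN, LT and MYC NTL, below the first quartile of every array (4.13 to 4.24), so its changes are not used as a measure of Nusap1.

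**Figure D1:**
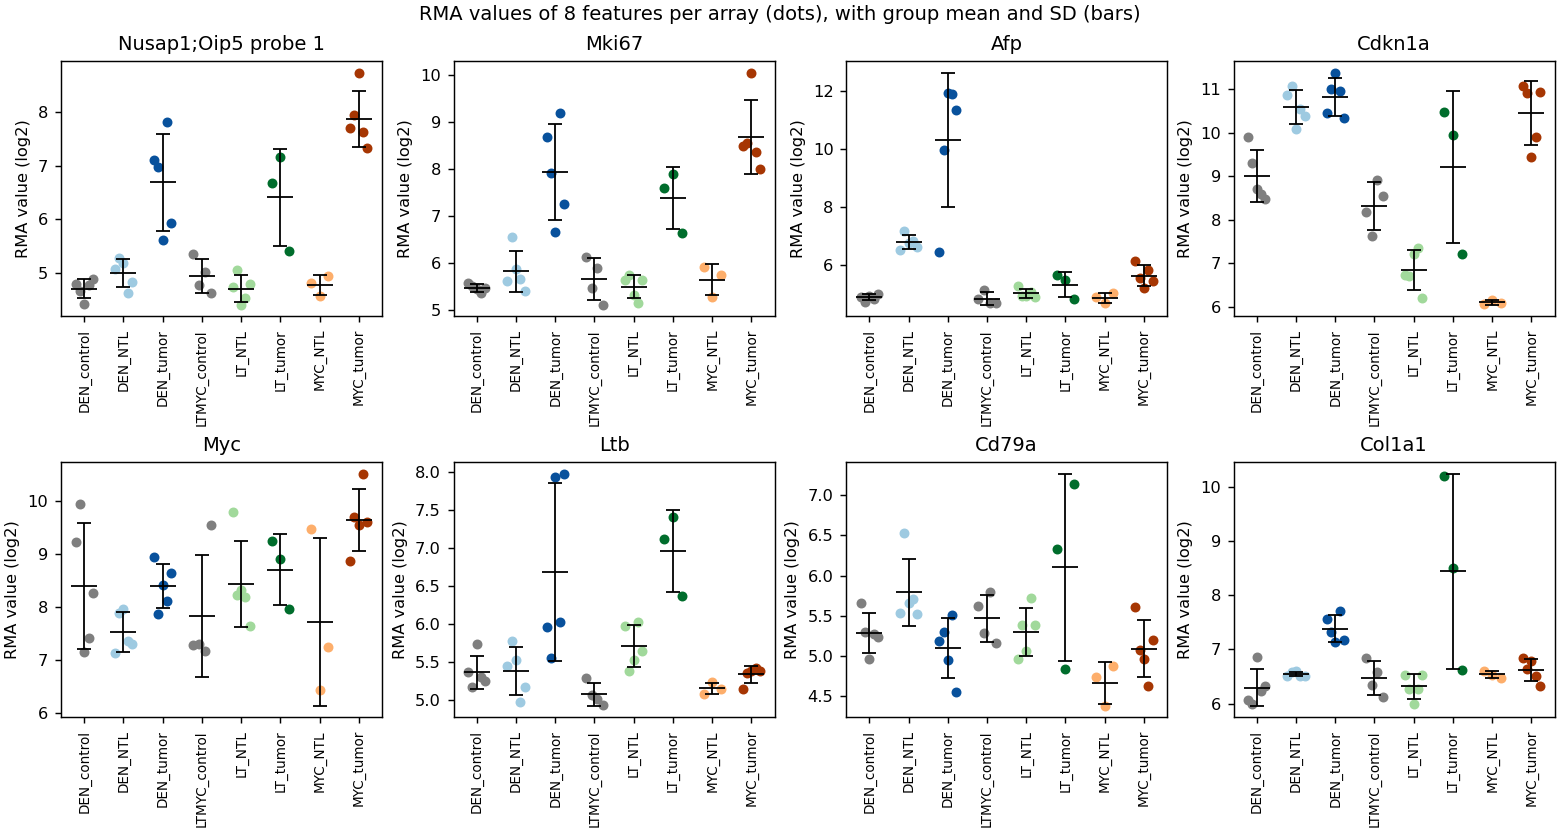
Log2 value of genes fixed before the data were examined on each of the 35 arrays, by group, with the group mean as a line and 1 standard deviation as a bar. The brighter Nusap1 and Oip5 probe set has its highest group mean, 7.87, in MYC tumors.

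DEN tumors were compared with NTL of the same model to see which genes mark carcinogen-induced tumors. Genes of fetal liver and liver tumors rose, and P450 and conjugation enzymes of hepatocytes fell. Gldn, encoding gliomedin, rose 22.3-fold (4.48 ± 0.13 log2 units, 5 against 5 arrays), Tmem54 by 4.13 ± 0.31, Cdh17, a cadherin, by 3.92 ± 0.52, Tspan8 by 3.76 ± 0.47 and Csn3, a casein, by 3.64 ± 0.61. Alpha-fetoprotein, Afp, rose by 3.54 ± 0.55 from an NTL mean of 6.79 ± 0.25, and glypican 3, Gpc3, by 3.10 ± 0.75. These 2 rises did not hold in every DEN tumor. The lowest tumor values, 6.445 for Afp and 6.353 for Gpc3, lay below the lowest NTL values, 6.532 and 6.961. Csn3 was 4.201 in DEN tumor replicate 1 and 9.648 to 10.227 in the other DEN tumors, so its rise comes from those. Asns, asparagine synthetase, and Psat1, of serine synthesis, rose by 3.83 ± 0.54 and 3.80 ± 0.30. The largest falls were those of Cyp4a14, a fatty acid hydroxylase, at -5.94 ± 0.78, Elovl3, a fatty acid elongase, at -5.83 ± 1.00, the sulfotransferase Sult2a8 at -5.40 ± 0.42 and Cyp2b10 at -5.37 ± 0.60. The organic anion transporter Slco1a1 fell by 4.76 ± 1.1, the carboxylesterases Ces3b and Ces1e by 4.29 ± 0.48 and 4.12 ± 0.33, and Etnppl by 4.11 ± 0.51. In all, limma called 6068 of 18820 genes, 2928 higher and 3140 lower, and 1110 of them changed at least 2-fold. The share of higher genes was 48.3%, and 41.5% with each array centred on its median.

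Of the gene lists in DEN tumors, 22 of 37 were called by camera with its preset correlation. The fetal and tumor markers (16 of 24 higher, 0 lower) and the P450 and conjugation enzymes (1 higher, 23 of 30 lower) held with an estimated correlation, at adjusted p = 0.0281 and 0.0397. Adjusted over the list alone, 16 and 1 fetal and tumor markers and 1 and 23 P450 and conjugation enzymes were called higher and lower. Akr1c18, Golm1 and Scd2 were among the fetal and tumor markers, at 2.88 ± 0.33, 3.28 ± 0.35 and 2.98 ± 0.35. Ces3a, Ugt2a3 and Cyp3a25 were among the enzymes that fell. Of the mitosis genes, 25 of 27 rose (27 adjusted over the list alone), with Mki67 at 2.11 ± 0.36, Aurkb at 1.61 ± 0.29 and Top2a at 1.60 ± 0.28, and the list had an adjusted p = 0.305 with an estimated correlation. DNA replication genes (15 higher and 1 lower of 27, 16 and 1 adjusted over the list alone, Mcm6 at 1.35 ± 0.23, Mcm10 at -0.88 ± 0.23) had an adjusted p = 0.305 with an estimated correlation as well. Among the stress lists, 12 of 23 ER stress genes rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 0.0687 with an estimated correlation). Of the immediate early genes, 10 of 16 rose, with Atf3 at 3.06 ± 0.31 and Btg2 at 2.75 ± 0.22 (10 and 1 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation). Of the p53 targets 9 rose and 3 of 22 fell, the same adjusted over the list alone (adjusted p = 0.417 with an estimated correlation).

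Several lists of liver metabolism had many lower members in DEN tumors, and cholesterol synthesis had higher ones, but none of the lists of this paragraph was called with an estimated correlation. Fatty acid oxidation lost 15 of 21 genes (16 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation), among them Acaa1b at -3.39 ± 0.26, Cpt2 at -1.30 ± 0.12 and Slc25a20 at -1.28 ± 0.12. Urea cycle and amino acid breakdown lost 15 of 26 (19 adjusted over the list alone, adjusted p = 0.283 with an estimated correlation). Bile acid synthesis and transport lost 16 of 23 and gained 2 (16 and 2 adjusted over the list alone, adjusted p = 0.0863 with an estimated correlation). Periportal genes had 3 higher and 10 of 21 lower (3 and 12 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation). Cholesterol synthesis rose in 9 of 18 genes, the same adjusted over the list alone, with Sqle at 1.63 ± 0.31 (adjusted p = 0.436 with an estimated correlation). Male-biased liver genes fell in 13 of 22 (14 adjusted over the list alone, adjusted p = 0.417 with an estimated correlation). Female-biased genes rose in 6 of 17 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation). No DEN tumor or NTL array had high Xist.

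Markers of other cells also moved in DEN tumors. Kupffer cell markers fell in 14 of 18 and rose in 1 (15 and 1 adjusted over the list alone), with Cd163 at -2.69 ± 0.37 (adjusted p = 0.305 with an estimated correlation). Sinusoidal endothelium lost 10 of 18 and gained 1 (12 and 2 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation). Vascular endothelium gained 16 of 20, the same adjusted over the list alone, with Esm1 at 2.66 ± 0.30 and Cd34 at 2.28 ± 0.33 (adjusted p = 0.283 with an estimated correlation). Cholangiocyte and ductular genes rose in 10 of 18 (12 adjusted over the list alone), with Prom1 at 3.49 ± 0.44 and Sox9 at 1.93 ± 0.24 (adjusted p = 0.157 with an estimated correlation). The keratin Krt19 of the fixed set did not rise, with means of 5.103 ± 0.39 in DEN tumors and 5.184 ± 0.115 in NTL. Interferon response genes rose in 15 of 28, the same adjusted over the list alone, with Usp18 at 1.78 ± 0.34 (adjusted p = 0.361 with an estimated correlation). NF-kB targets and chemokines had 13 higher and 1 lower of 30, the same adjusted over the list alone, with Icam1 at 1.24 ± 0.17 (adjusted p = 0.417 with an estimated correlation). Monocyte-derived cell markers had 8 higher and 1 lower of 21, the same adjusted over the list alone (adjusted p = 0.729 with an estimated correlation). T and NK cell markers had 1 higher and 5 of 28 lower (1 and 3 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation). The other 15 lists were not called. Their members higher and lower were 5 and 1 for ribosome biogenesis, 2 and 4 for glycolysis, 3 and 7 for lipogenesis, 10 and 2 for plasma proteins, 6 and 3 for acute phase, 0 and 6 for pericentral genes, and 0 and 0 for MHC class II. They were 1 and 6 for B cells, 8 and 4 for stellate cells and matrix, 1 and 2 for erythroid, 1 and 1 for acinar, 3 and 2 for adipocyte, 1 and 7 for NRF2 targets, 0 and 1 for clock and 0 and 0 for sex chromosome genes. The median and the mean of members differed in sign for ribosome biogenesis, glycolysis, erythroid and adipocyte genes. Col1a1 was called at 0.84 ± 0.33, and its call was lost in all 10 fits that left out an array, with an adjusted p of up to 0.103 without DEN tumor replicate 4.

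**Figure D2:**
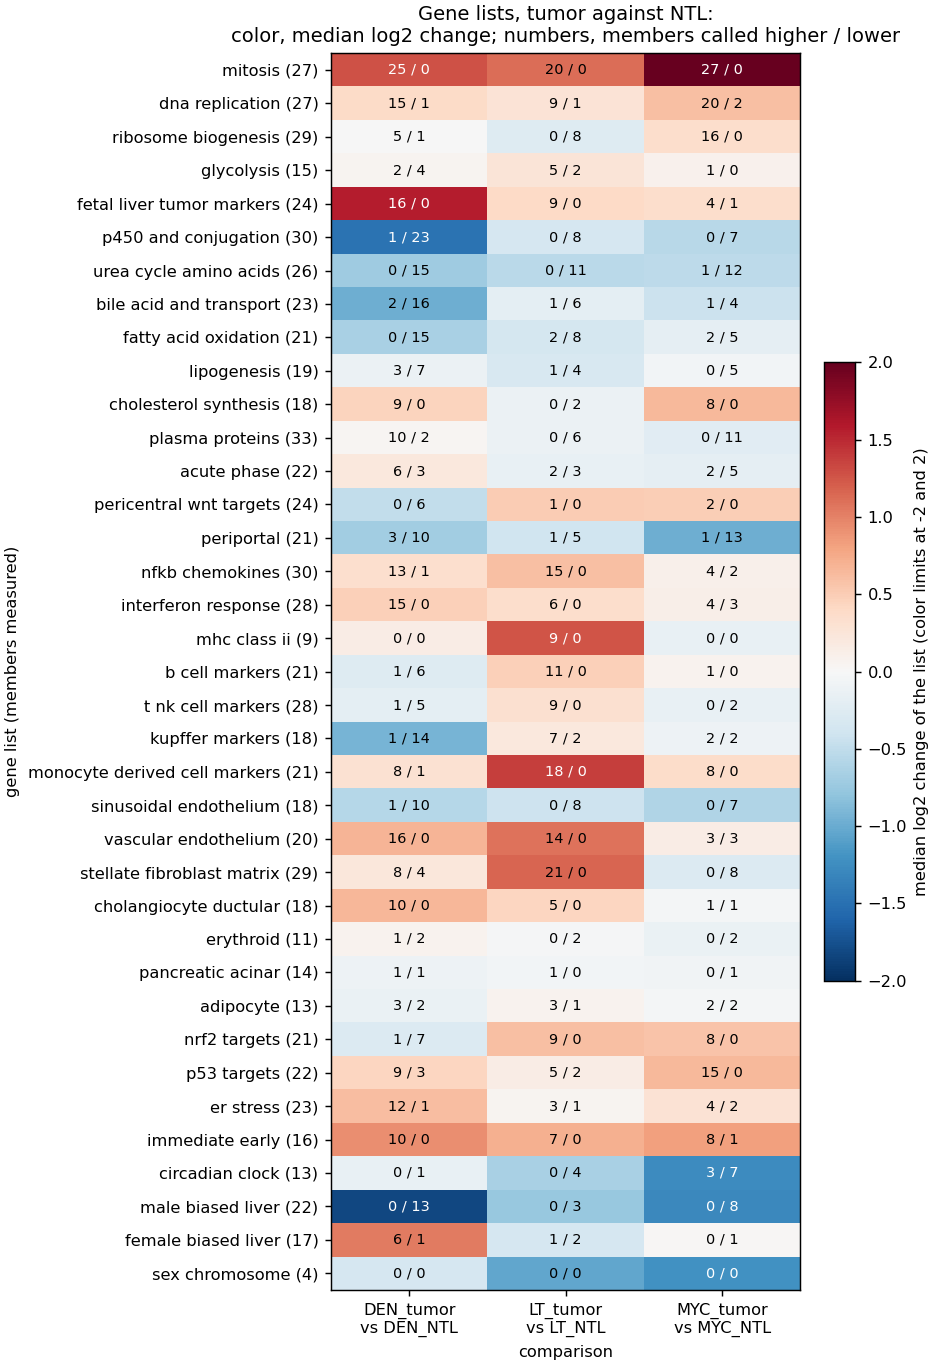
Median log2 change of the members of each gene list in tumor against NTL for the DEN, LT and MYC models, with the lists on the vertical axis. The mitosis list has medians of 1.27, 1.11 and 2.14.

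DEN controls give the background for both DEN tissues. Akr1c18, an enzyme of progesterone breakdown, rose by 5.32 ± 0.33 in NTL and by 8.20 ± 0.33 in tumors against controls, in which its mean was 4.25 ± 0.17 (5 arrays in each group). Klrb1b, a receptor of NK cells, rose by 2.78 ± 0.36 and 6.23 ± 0.36, and Gldn by 1.73 ± 0.13 and 6.21 ± 0.13. In tumors against controls Csn3 rose by 5.70 ± 0.61, Afp by 5.45 ± 0.55 and Gpc3 by 5.41 ± 0.75. Cyp2b10 fell by 5.88 ± 0.60, Sult2a8 by 4.89 ± 0.42, Ces3b by 4.30 ± 0.48, Sult5a1 by 4.17 ± 0.56 and Mfsd2a, a lipid transporter, by 4.13 ± 0.48. This comparison called 5775 genes, 2832 higher and 2943 lower. Of the fetal and tumor markers 17 of 24 were higher, also adjusted over the list alone (adjusted p = 0.00337 with an estimated correlation), and 23 of 30 P450 and conjugation enzymes were lower, 24 adjusted over the list alone (adjusted p = 0.0372 with an estimated correlation). In NTL, 37 genes were called, 13 higher and 24 lower. Scd2 rose by 1.88 ± 0.35, and Akap17b fell by 2.32 ± 0.17, Rnf24 by 2.28 ± 0.18, the chemokine Cxcl1 by 2.16 ± 0.40 and Gli2, a hedgehog transcription factor, by 1.92 ± 0.16. Lgals1 rose by 1.23 ± 0.26 and Cish fell by 1.90 ± 0.41, but these calls were lost without DEN control replicate 2 (adjusted p = 0.122) and without DEN NTL replicate 4 (adjusted p = 0.147). Gpc3, Afp and Cdkn1a had NTL differences of 2.31 ± 0.75, 1.91 ± 0.55 and 1.59 ± 0.41 that did not pass the test (adjusted p = 0.261, 0.189 and 0.116). The count in NTL was 183 when only the groups compared entered the fit.

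LT tumors were compared with NTL of the same mouse line, in which lymphotoxin drives chronic inflammation. Many genes of dividing cells, macrophages, matrix and vessels rose, although none of their lists was called with an estimated correlation (adjusted p = 0.3 for mitosis and 0.195 for the others). Ly6d rose 18.6-fold (4.21 ± 0.84 log2 units, 3 against 5 arrays), Cap2, an actin regulator, by 3.89 ± 0.55, the fatty acid elongase Elovl7 by 3.83 ± 0.75 and the hormone Fgf23 by 3.68 ± 0.70. The glycerol channel Aqp7 rose by 3.33 ± 0.61, thrombospondin 1, Thbs1, by 3.27 ± 0.55 and Bmp8b by 3.12 ± 0.66. Gpx2, a glutathione peroxidase, rose by 3.25 ± 0.85, a call lost without LT tumor replicate 2 (2.14, adjusted p = 0.102). Elovl7 was 11.07, 11.00 and 4.86, Fgf23 10.41, 10.85 and 4.88 and Gpx2 9.00, 10.09 and 4.54 in LT tumor replicates 1, 2 and 3, with NTL means of 5.14, 5.03 and 4.63, so these rises come from replicates 1 and 2, which share a mouse identifier stem. Other large changes also leaned on single arrays. Without LT tumor replicate 1 they were 3.408 for Ly6d, 2.539 for Aqp7, 2.237 for Thbs1, 2.347 for Bmp8b and -2.785 for Cyp2b10, with the calls kept. Cdkn1a, the cell cycle inhibitor p21, rose by 2.38 ± 0.48 and collagen Col1a1 by 2.12 ± 0.38 (1.24 without LT tumor replicate 1, with values of 10.21, 8.50 and 6.61 in replicates 1 to 3). The Cdkn1a mean was 9.21 in LT tumors, 6.84 in NTL and 8.32 in the shared controls, so NTL was itself below controls. The lowest tumor value of Cdkn1a, 7.22, lay within the NTL range of 6.19 to 7.34. Cyp2c54 fell by 3.85 ± 0.82 (2.52 without LT tumor replicate 3), Cyp2b10 by 3.82 ± 0.70, Pcp4l1 by 2.96 ± 0.62, Sdr9c7 by 2.73 ± 0.47 and Perp, a p53 target, by 2.69 ± 0.51 (1.47 without LT tumor replicate 2). Cyp2b13 fell by 3.70 ± 1.32, Serpina4-ps1 by 3.34 ± 1.13 and Raet1e by 2.77 ± 0.85, and these calls were lost without LT tumor replicate 2, LT NTL replicate 2 and LT tumor replicate 2 (adjusted p = 0.126, 0.105 and 0.122). Of the transgenes' mouse counterparts, Ltb rose by 1.25 ± 0.36 and Lta fell by 0.39 ± 0.13, calls lost without LT tumor replicate 2 (adjusted p = 0.081) and without LT tumor replicate 1 (adjusted p = 0.129).

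Limma called 3838 genes in LT tumors, 2006 higher and 1832 lower, and 803 changed at least 2-fold. The count was 1566 without LT tumor replicate 1, 5072 without LT tumor replicate 3 and 615 when only the groups compared entered the fit. It also fell with arrays of a shared mouse identifier stem averaged. With each array centred on its median the share of higher genes fell from 52.3% to 40.8%. LT tumor replicate 3 lay nearer to NTL: the median over the genes called higher was 0.30 above the NTL mean in it, against 1.13 and 0.68 in replicates 1 and 2, which share a mouse identifier stem. Of 159 called genes among those named by the fixed rule, 83 lost the call in at least 1 fit that left out an array, and the change of 59 moved more than 1.5-fold in such a fit.

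Inflammatory and stromal lists rose in LT tumors, and all LT tumors and 4 of 5 LT NTL arrays had high Xist. Camera called 25 of 37 lists with its preset correlation, and none of them with an estimated one. Monocyte-derived cell markers rose in 18 of 21 (20 adjusted over the list alone), with Lgals3 at 1.88 ± 0.32, Cx3cr1 at 1.56 ± 0.27 and Trem2 at 1.496 ± 0.22. Stellate cell and matrix genes rose in 21 of 29, also adjusted over the list alone, with Vim at 1.53 ± 0.25 and Col5a2 at 1.495 ± 0.18. Vascular endothelium rose in 14 of 20 (15 adjusted over the list alone), with Esm1 at 2.46 ± 0.34. MHC class II genes rose in 9 of 9, also adjusted over the list alone, with Ctss at 1.26 ± 0.25 and Ciita at 0.77 ± 0.15. B cell markers rose in 11 of 21 (16 adjusted over the list alone), with Ms4a1 at 1.35 ± 0.29 (0.84 without LT tumor replicate 3) and Cd79b at 1.27 ± 0.25. NF-kB targets and chemokines rose in 15 of 30, also adjusted over the list alone. Each of these 6 lists had an adjusted p = 0.195 with an estimated correlation. T and NK cell markers rose in 9 of 28 (13 adjusted over the list alone, adjusted p = 0.251 with an estimated correlation). Kupffer cell markers had 7 higher and 2 of 18 lower, also adjusted over the list alone (adjusted p = 0.567 with an estimated correlation). Interferon response genes rose in 6 of 28 (9 adjusted over the list alone, adjusted p = 0.521 with an estimated correlation). Mitosis genes rose in 20 of 27 (25 adjusted over the list alone), with Mki67 at 1.88 ± 0.41 and Aurkb at 1.47 ± 0.33 (adjusted p = 0.3 with an estimated correlation). DNA replication genes rose in 9 of 27 with 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.378 with an estimated correlation).

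Other lists called in LT tumors covered stress and metabolism. NRF2 targets rose in 9 of 21 (11 adjusted over the list alone), with Hmox1, heme oxygenase, at 1.61 ± 0.23 (adjusted p = 0.266 with an estimated correlation). Fetal and tumor markers rose in 9 of 24 and immediate early genes in 7 of 16, the same adjusted over the list alone, with Igf2bp3 at 1.98 ± 0.32 and Jun at 1.87 ± 0.36 (adjusted p = 0.198 for both with an estimated correlation). Jun differed by -1.64 in LT NTL against controls, so its NTL base was itself low. Cholangiocyte and ductular genes rose in 5 of 18, also adjusted over the list alone (adjusted p = 0.325 with an estimated correlation). Glycolysis genes had 5 higher and 2 of 15 lower (6 and 2 adjusted over the list alone) and p53 targets 5 higher and 2 of 22 lower, also adjusted over the list alone (adjusted p = 0.521 for both with an estimated correlation). Urea cycle and amino acid genes fell in 11 of 26 (14 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation). Fatty acid oxidation had 8 lower and 2 of 21 higher (11 and 2 adjusted over the list alone, adjusted p = 0.53 with an estimated correlation). P450 and conjugation enzymes fell in 8 of 30, also adjusted over the list alone, and ribosome biogenesis in 8 of 29 (9 adjusted over the list alone), with Rrp12 at -0.86 ± 0.12 and Nolc1 at -0.63 ± 0.13 (adjusted p = 0.449 for both with an estimated correlation). Plasma proteins fell in 6 of 33 (8 adjusted over the list alone, adjusted p = 0.654 with an estimated correlation). Periportal genes had 5 lower and 1 of 21 higher (6 and 1 adjusted over the list alone, adjusted p = 0.567 with an estimated correlation). Sinusoidal endothelium fell in 8 of 18 (9 lower and 1 higher adjusted over the list alone, adjusted p = 0.521 with an estimated correlation). Clock genes fell in 4 of 13, also adjusted over the list alone, with Hlf at -0.999 ± 0.19 and Per2 at -1.30 ± 0.29 (adjusted p = 0.195 with an estimated correlation). The other 12 lists were not called. Their members higher and lower were 1 and 6 for bile acid synthesis and transport, 1 and 4 for lipogenesis, 0 and 2 for cholesterol synthesis, 2 and 3 for acute phase and 1 and 0 for pericentral genes. They were 0 and 2 for erythroid, 1 and 0 for acinar, 3 and 1 for adipocyte, 3 and 1 for ER stress, 0 and 3 for male-biased, 1 and 2 for female-biased and 0 and 0 for sex chromosome genes. For acinar genes the median and the mean of members differed in sign.

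Against the shared controls, Cap2 rose by 4.46 ± 0.57 in LT tumors, Elovl7 by 4.02 ± 0.79 and Fgf23 by 3.54 ± 0.73 (3 against 4 arrays, with LT tumor replicate 3 near or below the control means of 4.96 and 5.17 in the last 2 genes), and Slco1a1 fell by 5.19 ± 1.33 and Elovl3 by 4.96 ± 1.21. Xist differed by 5.11 ± 1.48 and the Y-linked Eif2s3y by -4.07 ± 1.17, because all 3 tumors and 1 of 4 controls had high Xist. The calls of Xist and Eif2s3y were lost without LT tumor replicate 1 (adjusted p = 0.073 and 0.0693). Those of Sult1e1 (4.49 ± 1.43), Hsd3b5 (-4.21 ± 1.43) and Serpina4-ps1 (-4.28 ± 1.18) were lost without LT tumor replicate 2, control replicate 4 and control replicate 4 (adjusted p = 0.092, 0.173 and 0.0638). Limma called 3107 genes, 1652 higher and 1455 lower, and the share of higher genes fell from 53.2% to 45% with each array centred on its median. The count was 1032 without LT tumor replicate 1, 4542 without LT tumor replicate 3 and 1273 with the Xist level as a covariate. It also fell with arrays of a shared mouse identifier stem averaged. When only the groups compared entered the limma fit it was 0, with 3751 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0547.

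LT NTL was compared with controls to see what the transgene changes outside tumors, but 4 of 5 NTL arrays against 1 of 4 controls had high Xist. Ugt2b37 rose by 2.37 ± 0.49, the transglutaminase Tgm1 by 2.31 ± 0.39 and Cdh19 by 2.21 ± 0.41, and Cidea, a lipid droplet protein, fell by 3.73 ± 0.59 to a mean near the lower limit of the arrays. Polr1a, a subunit of RNA polymerase I, rose by 0.52 ± 0.09, and Jun and Dusp1 fell by 1.64 ± 0.34 and 1.46 ± 0.27. Female-biased liver genes rose in 2 of 17 (6 adjusted over the list alone) and male-biased genes fell in 1 of 22, also adjusted over the list alone, with medians of 1.49 and -0.89 (adjusted p = 0.419 and 0.945 with an estimated correlation). Ribosome biogenesis rose in 2 of 29 (10 adjusted over the list alone, adjusted p = 0.318 with an estimated correlation), and immediate early genes fell in 3 of 16 (5 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation). Further calls among the largest changes were lost without an array. This held for Usp2 (2.41 ± 0.58) and Npas2 (-2.49 ± 0.65) without control replicate 4 (adjusted p = 0.083 and 0.127). It also held for Fmo2 (1.95 ± 0.53) and Chrna4 (-2.95 ± 0.67) without control replicate 2 (adjusted p = 0.139 and 0.0817), and Elovl3 (-3.95 ± 1.06) and Cidec (-2.75 ± 0.74) without control replicate 1 (adjusted p = 0.122 and 0.176). In all 454 genes were called, 258 higher and 196 lower, 160 without control replicate 1 and 174 with the Xist level as a covariate. The count was 585 when only the groups compared entered the fit, and it was also higher with array quality weights. The share of higher genes moved from 56.8% to 65.9% with each array centred on its median. Ltb and Lta differed by 0.63 ± 0.33 and 0.22 ± 0.12 and did not pass the test.

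MYC tumors were compared with the arrays labelled as NTL of the MYC model, which may be wild-type liver by their identifiers. Many genes of cell division, ribosome biogenesis and the p53 response rose, and many of periportal hepatocytes fell, although these lists had adjusted p = 0.155, 0.265, 0.155 and 0.398 with an estimated correlation. Cdkn1a rose 20.6-fold (4.37 ± 0.48 log2 units, 5 against 3 arrays), Cplane1 by 4.13 ± 0.36, D17H6S56E-5 by 3.93 ± 0.43 and the tubulin Tubb2a by 3.79 ± 0.45. Mtmr11 rose by 3.68 ± 0.40, thyroxine-binding globulin Serpina7 by 3.49 ± 0.48, the kinase Pdk4 by 3.44 ± 0.54 and cyclin A2, Ccna2, by 3.38 ± 0.44. Myc itself rose by 1.94 ± 0.61 (adjusted p = 0.0217), a call lost without MYC NTL replicate 2 (1.29, adjusted p = 0.204). Serpina4-ps1 fell by 4.94 ± 1.13, Adh6-ps1 by 4.63 ± 0.65, Cyp2b10 by 4.48 ± 0.70 and the cholesterol hydroxylase Cyp46a1 by 4.19 ± 0.25. Clec2h fell by 3.98 ± 0.66, Cabyr by 3.94 ± 0.33, the clock repressor Ciart by 3.85 ± 0.80 and the deiodinase Dio1 by 3.48 ± 0.60. For some of these genes the tumors were near the shared controls and the arrays labelled MYC NTL were apart. In tumors against controls Tubb2a, Pdk4, Cabyr and Ciart differed by 0.12, 0.52, -0.19 and -0.46 and did not pass the test (adjusted p = 0.881, 0.506, 0.725 and 0.726). Clec2h and Serpina4-ps1 did not pass it either (adjusted p = 0.0598 and 0.0798), and Cdkn1a, Serpina7 and Cyp46a1 differed by 2.14, 1.22 and -1.68. Limma called 4106 genes, 2170 higher and 1936 lower, and 738 changed at least 2-fold. The share of higher genes was 52.8%, and 45.8% with each array centred on its median. The count was 2728 without MYC NTL replicate 1. Clock genes moved with the groups: Arntl was higher by 2.61 ± 0.49 and Per2 lower by 1.56 ± 0.29 in tumors than in NTL, and neither passed the test against controls (adjusted p = 0.94 and 0.281). With the difference of the clock arms as a covariate the count was 1767.

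Camera called 15 lists in MYC tumors with its preset correlation and none with an estimated one. Mitosis genes rose in 27 of 27, also adjusted over the list alone, with Prc1 at 2.97 ± 0.36 and Anln at 2.76 ± 0.36. DNA replication genes had 20 higher and 2 of 27 lower (24 and 2 adjusted over the list alone), with Mcm5 at 1.57 ± 0.18 and Mcm7 at 1.36 ± 0.13. The p53 targets rose in 15 of 22 (16 adjusted over the list alone), with Ckap2 at 2.49 ± 0.35 and Eda2r at 1.78 ± 0.32 (adjusted p = 0.155 for each of these 3 lists with an estimated correlation). Ribosome biogenesis, many of whose genes are known MYC targets, rose in 16 of 29 (18 adjusted over the list alone), with Npm1 at 0.74 ± 0.11 and Nob1 at 0.67 ± 0.11 (adjusted p = 0.265 with an estimated correlation). Cholesterol synthesis rose in 8 of 18 (10 higher and 1 lower adjusted over the list alone), with Hmgcs1 at 1.77 ± 0.29, but 0 of 18 were called in tumors against controls, where Hmgcs1 differed by 0.14 (adjusted p = 0.78). Monocyte-derived cell markers rose in 8 of 21, also adjusted over the list alone, with Mmp12 at 3.13 ± 0.48 (adjusted p = 0.48 for both with an estimated correlation). NRF2 targets rose in 8 of 21 (11 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). Immediate early genes had 8 higher and 1 of 16 lower (9 and 1 adjusted over the list alone), with Klf6 at 2.25 ± 0.27 (adjusted p = 0.398 with an estimated correlation). For some members of these lists MYC NTL was itself below controls, so their rise rests in part on MYC NTL. Pgd of the NRF2 targets differed by -0.953, Jun and Btg2 of the immediate early genes by -1.796 and -0.953. Plk2 of the p53 targets differed by -1.018, and Gsr of the NRF2 targets went the other way (0.593). In tumors against controls Mmp12 differed by 1.277 without control replicate 4 and Klf6 by 1.258 without control replicate 2, with the calls kept. Periportal genes had 13 lower and 1 of 21 higher (15 and 1 adjusted over the list alone), with Sult5a1 at -3.29 ± 0.64 and the arginase Arg1 at -1.68 ± 0.40. Urea cycle and amino acid genes had 12 lower and 1 of 26 higher, also adjusted over the list alone, plasma proteins 11 of 33 lower (14 adjusted over the list alone) and P450 and conjugation enzymes 7 of 30 lower (8 adjusted over the list alone). Each of these 4 falling lists had an adjusted p = 0.398 with an estimated correlation. Sinusoidal endothelium fell in 7 of 18 (11 adjusted over the list alone) and male-biased liver genes in 8 of 22 (9 adjusted over the list alone, adjusted p = 0.48 for both with an estimated correlation). Stellate cell and matrix genes fell in 8 of 29, also adjusted over the list alone, with Dcn at -1.64 ± 0.32 (adjusted p = 0.765 with an estimated correlation). The other 22 lists were not called. Among them, members higher and lower were 1 and 0 for glycolysis, 4 and 1 for fetal and tumor markers, 1 and 4 for bile acid synthesis and transport, 2 and 5 for fatty acid oxidation, 0 and 5 for lipogenesis and 2 and 5 for acute phase. They were 2 and 0 for pericentral genes, 4 and 2 for NF-kB targets and chemokines, 4 and 3 for interferon response, 0 and 0 for MHC class II, 1 and 0 for B cells, and 0 and 2 for T and NK cells. They were 2 and 2 for Kupffer cells, 3 and 3 for vascular endothelium, 1 and 1 for cholangiocyte and ductular genes, 0 and 2 for erythroid, 0 and 1 for acinar, 2 and 2 for adipocyte, 4 and 2 for ER stress, 3 and 7 for clock, 0 and 1 for female-biased and 0 and 0 for sex chromosome genes. The median and the mean of members differed in sign for fatty acid oxidation and adipocyte genes.

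Against the shared controls, H2-Ea, an MHC class II chain, and the protease Ctse were high in both MYC tissues. H2-Ea rose by 3.58 ± 0.39 in NTL (3 against 4 arrays) and by 4.72 ± 0.34 in tumors (5 against 4), and Ctse by 3.91 ± 0.61 and 4.65 ± 0.54. Whether MYC or another difference between these mice and the shared controls raised H2-Ea and Ctse was not tested. The rise of H2-Ea was not shared by other MHC class II genes. In tumors against controls H2-Ab1, H2-Eb1, H2-Aa and H2-Ob were called lower, with H2-Ab1 at -1.296 without control replicate 1. The calls of the last 3 were lost in some fits that left out an array. In tumors D17H6S56E-5 rose by 3.95 ± 0.39, Cplane1 by 3.73 ± 0.33 and the desmoglein Dsg1c by 3.38 ± 0.56. Cyp2b10 fell by 5.06 ± 0.64, Adh6-ps1 by 4.63 ± 0.60, the steroid enzyme Cyp17a1 by 4.13 ± 0.73, Cidea by 3.72 ± 0.59 and Plekhb1 by 3.66 ± 0.29. Tumors had 3860 genes called against controls, 1923 higher and 1937 lower, with 22 of 29 ribosome biogenesis genes higher and 15 of 18 sinusoidal genes lower, 22 and 17 adjusted over the list alone (adjusted p = 0.159 and 0.378 with an estimated correlation). In MYC NTL, Cabyr rose by 3.74 ± 0.35 and Asns by 3.50 ± 0.65, and Cidea fell by 3.78 ± 0.67, Tubb2a by 3.67 ± 0.47, Acnat2 by 3.12 ± 0.64 and Cdkn1a by 2.23 ± 0.50. Ciart rose by 3.39 ± 0.84, and Cyp2b9 and Cyp4a14 fell by 5.37 ± 1.44 and 3.99 ± 0.94, calls lost without MYC NTL replicate 2, replicate 1 and replicate 1 (adjusted p = 0.0759, 0.114 and 0.0616). Myc did not pass the test between NTL and controls (-0.12 ± 0.64, adjusted p = 0.968), and its sign changed without control replicate 4 (0.46), MYC NTL replicate 2 (0.53) or MYC NTL replicate 3 (0.12). Cholesterol synthesis fell in 4 of 18 genes (12 adjusted over the list alone, adjusted p = 0.474 with an estimated correlation), with Hmgcs1 at -1.64 ± 0.31. In MYC NTL 721 genes were called, 313 higher and 408 lower, 299 without MYC NTL replicate 1, 1537 when only the groups compared entered the fit and 2645 with array quality weights. Camera called 19 lists with its preset correlation, 4 higher and 15 lower, and none with an estimated one. The share of higher genes moved from 43.4% to 53.8% when each array was centred on its median.

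LT NTL and MYC NTL had 80 genes called in the same direction against the controls they share, 31 higher and 49 lower. Cidea fell from a control mean of 7.69 ± 2.59 to 3.97 and 3.92, below the first quartile of every array, and Tubb2a by 2.39 and 3.67 in LT and MYC NTL. Jun changed by -1.64 and -1.796, and Usp2 by 2.41 and 2.66. Shared controls alone link both sets of changes: over 100 simulations of unchanged groups the correlation across genes was 0.488 on average, against 0.181 observed. The covariance was 0.0161 in the simulations and 0.0151 observed, so shared controls alone give a covariance of this size. In the simulations 0 genes were called in both, but no gene was changed in them, so this cannot tell whether shared controls explain the overlap. With the controls divided between both comparisons, the overlap was between 6 and 12 genes. These fits had fewer controls and called fewer genes, 50 to 194 in LT NTL and 196 to 468 in MYC NTL, so lost power may account for part of the drop. The overlap was 33 without MYC NTL replicate 2, and it also fell with the Xist level as a covariate. It was 179 when only the groups compared entered the fit and 513 with array quality weights.

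The 3 tumor to NTL comparisons share no array, and they were intersected to see what the models have in common. Ly6d rose by 2.77 ± 0.73, 4.21 ± 0.84 and 2.70 ± 0.84 in DEN, LT and MYC tumors, D17H6S56E-5 by 3.14 ± 0.37, 2.59 ± 0.43 and 3.93 ± 0.43, and Mtmr11 by 3.17 ± 0.34, 1.803 ± 0.40 and 3.68 ± 0.40. Esm1, an endothelial gene, rose by 2.66 ± 0.30, 2.46 ± 0.34 and 2.84 ± 0.34, the amino acid transporter Slc1a4 by 2.77 ± 0.51, 1.88 ± 0.59 and 3.18 ± 0.59, and the annexin Anxa2 by 2.86 ± 0.38, 2.45 ± 0.43 and 2.47 ± 0.43. Ccna2 and Mki67 had mean rises of 2.38 and 2.34 over the models. Cyp2b10 fell by 5.37 ± 0.60, 3.82 ± 0.70 and 4.48 ± 0.70, and Sult2a8 by 5.40 ± 0.42, 2.62 ± 0.48 and 2.66 ± 0.48. Without LT tumor replicate 1 the LT changes were 3.408 for Ly6d, -2.785 for Cyp2b10 and -2.197 for Sult2a8, with the calls kept. The bile acid enzyme Cyp8b1, Sult5a1, Ces3b, Cyp2f2, Slc15a5 and Ces1e had mean changes of -3.09, -2.99, -2.84, -2.82, -2.44 and -2.43. Of the mitosis genes 20 of 27 rose in all 3 models, and 6 urea cycle and amino acid genes and 4 bile acid genes fell in all 3. In total 334 genes were higher and 293 lower in all 3, against 36 and 31.4 for independent lists, although genes are not independent of each other. Without LT tumor replicate 1 the counts were 180 and 136, and without LT tumor replicate 3 they were 514 and 445. They were 53 and 45 when only the groups compared entered the fit, and 211 and 188 with arrays of a shared mouse identifier stem averaged. Single calls were lost in LT for Slc1a4, Ces1e, Ces3b and Sult5a1 without LT tumor replicate 1 (changes of 1.42, -0.77, -1.21 and -1.24, adjusted p = 0.206, 0.306, 0.233 and 0.313) and for Ccna2, Cyp8b1 and Cyp2f2 without LT tumor replicate 2 (changes of 1.32, -1.24 and -1.09, adjusted p = 0.0551, 0.346 and 0.385). In MYC they were lost for Ly6d without MYC NTL replicate 3, Slc15a5 without MYC NTL replicate 2 and Cyp2f2 without MYC tumor replicate 2 (changes of 2.485, -1.42 and -1.815, adjusted p = 0.081, 0.129 and 0.0948). Across all genes the changes of DEN and LT tumors correlated with r = 0.453, of DEN and MYC with 0.431 and of LT and MYC with 0.413.

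The differences between the tumor to NTL changes were tested to see where the models part. All LT tumors and most LT NTL arrays had high Xist, and no DEN or MYC tumor or NTL array did. Differences that involve LT therefore cannot separate model from sex. Afp rose more in DEN than in LT tumors (difference 3.25 ± 0.85) and than in MYC tumors (2.77 ± 0.85), the second a call lost without MYC NTL replicate 3 (adjusted p = 0.0579). Gldn differed by 3.93 ± 0.20 and 4.53 ± 0.20 in the same comparisons. Cyp4a14 and the fatty acid transporter Cd36 changed by -6.40 ± 1.19 and -4.26 ± 0.46 in DEN relative to MYC tumors, and the cadherin Cdh1 by 5.34 ± 0.93. Col1a1 rose more in LT than in MYC tumors (2.05 ± 0.53, and 1.16 without LT tumor replicate 1, adjusted p = 0.0478), and Serpina7 and Acnat2 changed by -4.63 ± 0.68 and -4.88 ± 0.87 in LT relative to MYC. Cdkn1a rose less in DEN than in MYC tumors (-4.13 ± 0.63), but its tumor means were close, at 10.82 and 10.46. Its NTL means were 10.59 in DEN and 6.09 in MYC, with 8.32 in the shared controls, so the difference lies in NTL. The arrays labelled MYC NTL, which may be wild-type by their identifiers, also differed from controls by -3.99 for Cyp4a14 and -3.12 for Acnat2. B cell markers were lower in the change of DEN relative to LT tumors in 14 of 21 and T and NK cell markers in 11 of 28, 16 and 16 adjusted over the list alone (adjusted p = 0.186 for both with an estimated correlation). Stellate cell and matrix genes were higher in LT relative to MYC in 19 of 29 (25 adjusted over the list alone, adjusted p = 0.384 with an estimated correlation). Ribosome biogenesis was lower in 19 of 29 (21 adjusted over the list alone, adjusted p = 0.301 with an estimated correlation). NRF2 targets were lower in the change of DEN tumors relative to LT in 8 and relative to MYC in 10 of 21, 13 and 16 adjusted over the list alone (adjusted p = 0.211 and 0.358 with an estimated correlation). Between DEN and LT 2618 genes differed, between DEN and MYC 2841 and between LT and MYC 2326. The Nusap1 and Oip5 probe set rose less in DEN than in MYC tumors (-1.42 ± 0.47), a call lost without MYC NTL replicate 2 (adjusted p = 0.104).

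**Figure D3:**
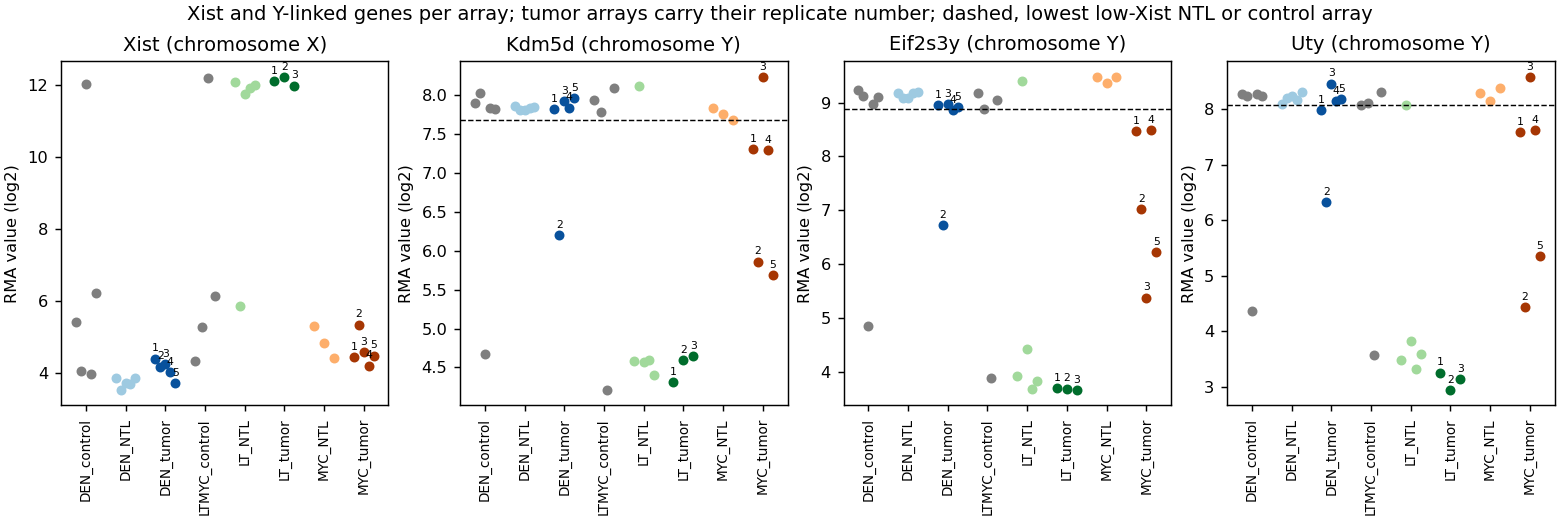
Log2 value of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 35 arrays, by group. Xist is above 11.7 in 9 arrays and at most 6.24 in the others.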

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

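Among 157 groups of values of fixed and named genes, 13 held an array far from the rest of its group, and 7.8 were expected because about 1 in 20 by chance would. MYC tumor replicate 3 stood apart for Mki67 (10.04), Glul (9.41) and Serpina4-ps1 (9.41). DEN tumor replicate 1 did for Tspan8 (6.91) and Csn3 (4.20), and LT NTL replicate 2 for Pcp4l1 (6.65) and Cyp2b13 (4.14). The others were Myc in replicate 4 of the shared controls (9.56), Ltb in MYC tumor replicate 1 (5.15), Cd79a in DEN NTL replicate 2 (6.53), Cyp4a14 in DEN NTL replicate 4 (12.33), and the dimmer Nusap1 and Oip5 probe set in DEN control replicate 2 (3.81) and LT NTL replicate 1 (3.60).

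The tumor to NTL change differed between DEN and LT in 2618 genes, between DEN and MYC in 2841 and between LT and MYC in 2326. In DEN relative to LT the differences were 6.57 for Cyp2b13, 5.62 for Cyp2b9, 4.26 for Cyp39a1, 3.97 for Tmem54, 3.93 for Gldn, 3.25 for Afp, -1.49 for Cd79a, -2.14 for Cdkn1a, -4.24 for Cyp2c55, -4.47 for Csad, -4.78 for Nat8, -4.83 for Elovl3 and -5.16 for Snhg11. The calls of Cyp2b9 and Cd79a were lost without LT tumor replicate 3 (adjusted p = 0.0936 and 0.0772), that of Cdkn1a without LT tumor replicate 1 (0.122) and that of Elovl3 without LT tumor replicate 2 (0.105). Model and sex are not separated here, since Xist was high in most LT arrays and in no DEN tumor or NTL array. Cyp2b9 is on the female-biased list. Cyp2b13 was 4.14 in LT NTL replicate 2, which had low Xist, and 10.11 to 10.72 in the other LT NTL arrays.

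In DEN relative to MYC the differences were 5.34 for Cdh1, 5.25 for Adgrf1, 4.53 for Gldn, 4.32 for Rdh16f2, 4.32 for Asns, 2.77 for Afp, -1.42 for the Nusap1 and Oip5 probe set, -4.13 for Cdkn1a, -4.18 for Cplane1, -4.26 for Cd36, -4.49 for Fitm1 and -6.40 for Cyp4a14. In LT relative to MYC they were 4.45 for Clec2h, 4.21 for Adh6-ps1, 4.01 for Cabyr, 3.47 for Slc22a7, 3.40 for Fgf23, 2.05 for Col1a1, -3.01 for Sdr9c7, -3.62 for Serpinb1a, -4.29 for Cplane1, -4.63 for Serpina7 and -4.88 for Acnat2. The call of Fgf23 was lost without LT tumor replicate 1 (adjusted p = 0.112). For some of these genes the arrays labelled MYC NTL were themselves apart from the shared controls. They differed by 3.50 for Asns, 3.74 for Cabyr, -2.23 for Cdkn1a, -3.12 for Acnat2 and -3.99 for Cyp4a14, so these differences rest in part on MYC NTL.

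Probe sets outside the tested genes were also called in tumors against NTL: 2696 in DEN, 1025 in LT and 1912 in MYC. They carry several gene symbols or none in the annotation used here.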

How the results depend on the processing

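Counts of called genes moved with several settings, given here with the values. The cause was not tested. The Xist covariate, the permutation test and the splits with arrays of a shared stem averaged, the fit without the high-Xist controls, the fit with only the high-Xist LT arrays and the clock covariate were chosen after the data were seen, and all other settings were fixed before.

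When only the groups compared entered the fit, genes called were 183 for DEN NTL against controls (37 before), 615 for LT tumor against NTL (3838), 0 for LT tumor against controls (3107), 1537 for MYC NTL against controls (721) and 1231 for the LT to MYC difference (2326). The genes shared by all 3 models were 53 higher and 45 lower (334 and 293), and LT and MYC NTL overlapped in 179 genes (80). The Nusap1 and Oip5 probe set lost its LT call against controls, with an adjusted p of 0.158 in place of 0.00761 (the change, 1.47, is the same by construction).

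With array quality weights the counts were 297 for DEN NTL against controls, 2019 for LT tumor against NTL, 1447 for LT tumor against controls, 2013 for LT NTL against controls, 2645 for MYC NTL against controls, 1719 for the DEN to LT difference, 4388 for the DEN to MYC difference and 513 for the overlap. With arrays of a shared mouse identifier stem averaged they were 74 for DEN NTL against controls, 2311 and 1616 for LT tumor against NTL and controls, 211 and 188 for genes shared by the models, higher and lower, and 121 for the overlap.

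At an adjusted p under 0.01 the counts were 21 for DEN NTL against controls, 2088, 1284 and 114 for LT tumor against NTL, LT tumor against controls and LT NTL against controls, and 2264, 2247 and 303 for the same MYC comparisons. They were 1174, 1506 and 892 for the DEN to LT, DEN to MYC and LT to MYC differences, 138 and 98 for the shared genes and 24 for the overlap. With a fold of at least 2 required as well as an adjusted p under 0.05, the DEN counts were 1110, 1230 and 17 for tumor against NTL, tumor against controls and NTL against controls, the LT counts 803, 654 and 59, and the MYC counts 738, 700 and 176. The differences between models had 807, 841 and 644, the shared genes were 85 and 38, and the overlap was 19.

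With the Xist level as a covariate the counts were 1273 for LT tumor against controls, 174 for LT NTL against controls and 41 for the overlap. Without the high-Xist controls MYC NTL had 452. With only the high-Xist LT arrays LT tumor against NTL had 3446. With the clock covariate MYC tumor against NTL had 1767. With the controls divided between LT and MYC NTL the overlap was 8, 12, 10, 6, 6 and 12. With the correlation estimated per list, 2, 0 and 0 lists were called in DEN, LT and MYC tumors against NTL, where the preset correlation gave 22, 25 and 15.

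Leaving out each array in turn gave 1566 to 5072 genes for LT tumor against NTL, 1032 to 4542 for LT tumor against controls, 160 to 586 for LT NTL against controls, 2728 to 3995 for MYC tumor against NTL and 299 to 660 for MYC NTL against controls. The genes shared by all 3 models ranged from 180 to 514 higher and 136 to 445 lower, and the overlap from 33 to 86. The Nusap1 and Oip5 change in LT tumors against controls ranged from 1.099 to 1.98, with an adjusted p of 0.0706 without LT tumor replicate 2.

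Of the values of named genes that were called, 1 changed sign: Kdm5d in LT tumors against controls, 0.14 with the Xist covariate (adjusted p = 0.892). Over all settings 2504 of 23259 calls of named genes were lost, and 80 of 3382 values not called became called. For lists in tumor against NTL and NTL against controls, 97 calls were lost and 2 kept with the correlation estimated per list. Fry, which asks whether a list moves on balance and does not compare it with other genes, kept 54 and lost 45. Over the fits without an array, 766 list calls were kept and 81 lost.

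Mice of equal replicate number were not treated as pairs. Of 35 pairs with the same number over the 9 comparisons of groups, NTL against controls included, 10 correlated above 0.1, and LT tumor against controls was the only comparison, with r from 0.137 to 0.233, in which every pair did. Values are array intensities, in which small changes of dim genes and changes of very bright genes such as Alb are compressed.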

Other observations

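The pericentral gene list was examined array by array after the result was seen. Genes next to the central vein, which Wnt signalling maintains in liver, split the tumors. In MYC tumor replicates 1, 2, 4 and 5, Glul, glutamine synthetase, was between 13.43 and 13.52 against 12.45 ± 0.08 in NTL, and Lgr5, a Wnt receptor component, between 9.84 and 10.18 against 7.57 ± 0.22. In MYC tumor replicate 3 Glul was 9.41 and Lgr5 5.21, and 0 of 24 members lay above the NTL mean, against 19 to 21 in the others. DEN tumor replicates 3 and 5, which share a mouse identifier stem, had 17 of 24 members above the NTL mean, and DEN tumor replicates 1, 2 and 4 had 3, 2 and 3. LT tumor replicates 1 and 2 had 18, and replicate 3 had 12. The group tests of this list, which average over such arrays, were not called in any model.

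The Xist covariate was chosen after Xist was seen to split the arrays, and what it would do to the sex-biased lists was written before that result was seen. LT NTL carried high Xist in 4 of 5 arrays and its controls in 1 of 4. Female-biased liver genes had a median change of 1.49 and male-biased genes -0.89, a gap of 2.38. With the Xist level as a covariate the medians were 0.249 and 0.081 and the gap was 0.168, 7% of the first, which is consistent with the sex of the animals as the source of the gap. For the lymphotoxin transgene, the test written before asked whether the 1 LT NTL array with low Xist lies outside the range of the low-Xist controls. The mean of its female-biased genes minus that of its male-biased genes was -2.50, against -2.33 to -0.684 in 3 low-Xist controls. This is outside the range, on the side opposite to the gap, and with 1 array a part of the transgene stays open.

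Tests of the clock were chosen after the result was seen. The median change of the negative clock arm minus that of the positive arm was 2.43 in MYC NTL against controls and -2.39 in MYC tumors against NTL. It was 1.44 in LT NTL, 1.25 in LT tumors and -0.33 in MYC tumors against the same controls, and -0.875 in DEN NTL and -1.33 in DEN tumors against theirs. A shift is thus not limited to MYC NTL, although the LT and MYC values share their controls and are not independent. Over deviations of 35 arrays from their group means the arms were opposed, with r = -0.891, rho = -0.838, a permutation p of 1e-05 (the smallest possible) and r = -0.857 without the farthest arrays. Opposition within groups shows how the arms move together, whatever shifts them. It cannot tell a different time of day at collection from other causes of the group shifts. A different time of day for several groups, MYC NTL among them, stays possible. If the MYC transgene in NTL disturbed the clock, Myc would be higher in NTL than in controls. It was -0.117 ± 0.64 (adjusted p = 0.968), which cannot tell, since it was 0.457 without control replicate 4, and since the probe set need not detect the transgene and these mice may be wild-type by their identifiers.

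Tests of the Y-linked genes were chosen after the result was seen. Kdm5d, Eif2s3y and Uty were all below the lowest of 16 male NTL and control arrays in 5 of 10 male tumor arrays. In MYC tumor replicates 1 and 4 they were only 0.365 to 0.484 lower. DEN tumor replicate 2 was lower by 2.15 for Eif2s3y, and MYC tumor replicates 2 and 5 by 1.86 and 2.66. A swapped label or female animal would bring high Xist. Its highest value was 5.347 in the arrays with all 3 genes more than 1 log2 unit low, which argues against that. A weaker signal of those arrays would lower genes of equal brightness alike, but at most 0.73% of such genes lay as far below their lowest male NTL or control array, which argues against that. Loss of Y-linked DNA or its silencing in tumor cells could give the pattern, and RNA cannot separate them. In MYC tumor replicate 3 only Eif2s3y was low. The smaller distance of its neighbors Kdm5d and Uty from the lowest male array was 0.513, above it, which argues against loss of the chromosome there.

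Splits were written before the result was seen, apart from those with arrays of a shared stem averaged, chosen after: arrays of the compared groups were regrouped and the count of called genes taken again, to ask only whether chance can be excluded. In DEN the real counts for tumor against NTL, tumor against controls and NTL against controls were 6068, 5775 and 37, and the highest of the other splits 2182, 2477 and 7. In LT they were 3838, 3107 and 454 against 2240, 1450 and 17. In MYC they were 4106, 3860 and 721 against 1248, 2203 and 230. The differences between models were 2618, 2841 and 2326 against 199, 89 and 36. For these only tumor arrays were regrouped, each shifted by the NTL means, and NTL arrays stayed in place. The error of the NTL means counts in full in the real grouping and is diluted in the others, so these splits cannot exclude chance for the differences. The genes shared by the models were 334 and 293 against 0 and 0. These splits remove the tumor effect in every model at once. They therefore cannot tell whether the models share more genes than unrelated tumor changes would. For the overlap of LT and MYC NTL, 80, another split gave 137 and 3 of 100 were as large. For lists the real counts were 22, 25 and 15 in DEN, LT and MYC tumors and the highest others 23, 23 and 18, so chance is not excluded for the count of called lists in DEN (7 of 100 as large) and MYC (12 of 56).

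Those splits take every array as an animal, and the splits with arrays of a shared mouse identifier stem averaged were chosen after the result was seen. In DEN tumors against NTL and controls the counts were then 5375 and 5245, and the highest others 357 and 1283, in 56 splits each. In LT tumors against NTL the count was 2311 against 523 in 21 splits. The DEN to MYC difference had 2895 against 219, the LT to MYC difference 2273 against 198, and the genes shared by the models 211 and 188 against 0 and 0, so for these counts 1 split, the real one, was as large. The limits given above for splits of differences between models and of genes shared by the models hold here too. For LT tumors against controls (1616, highest other 108) and the DEN to LT difference (2057, highest other 236) 15 and 10 splits are too few for a share under 0.05. For called lists the counts were 22 in DEN and 23 in LT, and the highest others 25 and 25, so chance is not excluded for either (5 of 56 and 2 of 21 as large).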
